A study of Rattus norvegicus with 9 samples.

How the data were processed

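Small RNA libraries had been made from total RNA of cultured rat cartilage progenitor cells and sequenced from 1 end. The 9 libraries fall into 3 groups of 3, taken from the sample labels: passage 3 cells (P3), passage 9 cells (P9) and passage 3 cells with FFSS (FFSS). Per the submitters' design text, P3 is the control, P9 the replicative senescence group and FFSS flow fluid shear stress. The deposited table gave a read count for each of 726 miRNA rows in each library, per the file headers. It also gave a TPM value for each, per the file headers, which equalled the count scaled by the library's total in the table (CPM) with a largest difference of 4.85e-05, so no length term had entered it. Bowtie and the build Rnor_6.0 are named in the submitters' processing notes, without a version for Bowtie. The counting program, the miRNA annotation release and the program that predicted 91 of the 726 rows are not given in the sources used here; the other 635 rows carry annotated rat names. All count and TPM columns belonged to a labelled library.

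Counts were tested as deposited with edgeR 4.0.16 and limma 3.58.1 in R 4.3.3. Rows were kept by filterByExpr, which left 439 miRNAs, 7 of them predicted, and removed 0.0069% of the reads. Libraries were scaled by TMM. One model without intercept held all 9 libraries, so that the groups shared 1 estimate of the spread, and the contrasts P9 against P3, FFSS against P3 and P9 against FFSS were tested with the robust edgeR quasi-likelihood test. A miRNA was called at a Benjamini-Hochberg adjusted p under 0.05 over the 439. Levels are given as CPM of the library total with SD over 3 libraries, and changes as log2 fold changes with their standard errors (SE). An adjusted p of a single miRNA comes from this edgeR test unless another tool or scale is named with it. For a miRNA with 0 reads in a group, the fold is a bound against 3 counts over the group. Intervals and bounds cover counting error only.

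Some rows share reads. In 29 pairs, covering 58 rows with a mean of at least 10 counts, the counts of both rows agreed in every library within 10% or 5 reads, as for miR-378a-3p and miR-3557-5p. How the counter divided reads between such rows is not given in the sources used here, so these rows are uncertain individually and are named as a pair. The filter kept 410 distinct rows once pairs were merged.

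The choice of tests, lists and naming rule was made before the data were examined. Named are miR-708-5p and miR-708-3p. For each comparison with P3, named are also the 10 called miRNAs with the highest and the 10 with the lowest log2 fold change, among those with a mean of at least 50 CPM in the higher group and no overlap of the groups in CPM (5 each way for P9 against FFSS). The rule further takes up to 5 miRNAs per direction changed in both comparisons, up to 4 members of a list with the smallest p, 3 hairpins and the 5 miRNAs with the most reads. Other miRNAs, named where a count was small or where they stood out, were chosen after their values were seen.

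Of 24 lists, 20 had at least 3 measured members and were tested with camera at a preset correlation of 0.01, two-sided, with Benjamini-Hochberg adjustment over the 20. The tested lists were miRNAs reported up in senescence, the miR-34 family, the miR-17-92 clusters, chondrocyte and cartilage miRNAs, miRNAs reported as shear or stretch responsive, the let-7 and miR-98 family, the Dlk1-Dio3 locus, the miR-322 and miR-503 cluster, the miR-29, miR-15/16, miR-30 and miR-181 families, the miR-23/27/24 clusters, fibroblast and smooth muscle miRNAs, miR-221 and miR-222, NF-kB and inflammation miRNAs, and markers of blood, epithelium, muscle and the nervous system. The miR-708, hypoxia, endothelium and liver lists had fewer than 3 measured members and were read by member. Camera with an estimated correlation and the rotation test fry were alternatives. Counts are given over all 439 miRNAs and adjusted over the list alone. The lists overlap: 11 of the 13 senescence miRNAs and 15 of the 16 shear or stretch miRNAs are also in another list.

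For 89 hairpins with a mean of at least 20 counts on each arm, the log2 ratio of 5p to 3p counts, each with 0.5 added, was compared with limma. This ratio does not depend on scaling between libraries. For the overlap of both comparisons with P3, 100 simulations drew unchanged groups against the same controls. Alternatives were other scalings (DESeq2 size factors, upper-quartile factors, library size, TMM without the 10 most abundant miRNAs), no filter or a mean of at least 50 counts, DESeq2 1.42.0, limma-voom, limma-trend on log2(TPM + 1) and log2(TPM + 10), fits of only the 2 groups compared, a replicate block, a required absolute log2 fold change of 1, and leaving out each library. Merging near-identical rows and thinning all libraries to the smallest total, with the filter applied again or with the miRNAs of the full counts kept, were chosen after seeing the data. Simulated counts with known changes were used to test each step. For the edgeR step 200 of the 439 miRNAs were changed. So many changes ease the adjusted threshold, so the shares below need not hold where fewer miRNAs change. The edgeR step recovered 45.4% of 2-fold and 89.6% of 4-fold changes for P9 against P3 (425 miRNAs), 46.4% and 91.8% for FFSS against P3 (423 miRNAs), and 36.1% and 92.7% for P9 against FFSS (425 miRNAs), with 1 of 131, 1 of 135 and 2 of 126 calls false. Camera called the 1 list moved among 20 (439 miRNAs, P9 against P3) and no other, and the arm step recovered 15 of 19 hairpins moved 4-fold among 88 (FFSS against P3) with 0 false calls. Members of these simulated lists were drawn at random without correlation, so lists whose members vary together were not tested. No sequence was used here, so GC content was not examined, and a genome build served only for the positions of miRNA genes.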

Results

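miRNA levels were measured by small RNA sequencing in cartilage progenitor cells, primary wild-type cultures from rat condylar cartilage. Serial passage of cultured cells leads to replicative senescence, a lasting stop of division, and flow fluid shear stress is the drag of moving medium over the cells. The 3 groups were P3, P9 and FFSS, with 3 libraries each. The miRNA reads per library came to 8410730, 7522702 and 8862560 in P3, 7614513, 7867438 and 8177357 in P9, and 2878910, 7082142 and 3896403 in FFSS, so FFSS replicates 1 and 3 were the shallowest. Between 512 and 617 of the 726 rows had reads in a library. The labels do not say whether replicates came from separate cultures or animals, so all p-values measure only the spread between these samples, which may be technical. The 5 miRNAs with the most reads were miR-21-5p, miR-148a-3p, miR-143-3p, miR-99a-5p and miR-27b-3p, and the top 5 of a library held 47.7% to 63.1% of its reads. The correlation of log CPM across miRNAs was 0.985 to 0.992 between P3 replicates. It was 0.994 between P9 replicates 1 and 2 but 0.956 and 0.963 with P9 replicate 3. P9 replicate 3 correlated more closely with P3 replicate 2, at 0.969, and at 0.956 and 0.946 with P3 replicates 1 and 3. FFSS replicate 1 reached 0.962 and 0.971 with the other FFSS libraries, which correlated at 0.986.

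The series title concerns miR-708-5p, and both arms of this hairpin, which lies in an intron of a teneurin gene, were read first. At passage 9 both arms fell. miR-708-5p went from 62.2 ± 25.4 CPM in P3 to 15.5 ± 8.73 CPM in P9 (SD, n = 3; log2 fold change -1.94, SE 0.53, adjusted p = 0.0419), and miR-708-3p from 78.6 ± 10.4 to 14.9 ± 6.27 CPM (-2.31, SE 0.43, adjusted p = 0.00395). Under shear stress miR-708-5p stood at 25.4 ± 13.9 CPM (-1.32, SE 0.52, adjusted p = 0.0898) and miR-708-3p at 105 ± 53.7 CPM (0.33, SE 0.41, adjusted p = 0.564), and neither passed the test. The groups differed directly for miR-708-3p (P9 against FFSS -2.64, adjusted p = 7.24e-04) and not past the test for miR-708-5p (-0.63, adjusted p = 0.359). The call on miR-708-5p at passage 9 was lost without P3 replicate 1 (adjusted p = 0.150), P3 replicate 3 (0.138), P9 replicate 1 (0.0565), P9 replicate 2 (0.0797) or FFSS replicate 3 (0.0695), with a mean of at least 50 counts (0.0633), on log2(TPM + 1) (0.0501) and with the replicate block (0.0722). Under shear stress it passed without P9 replicate 3 (adjusted p = 0.0174), with no filter (0.0437), in DESeq2 (0.0479) and in a fit of only P3 and FFSS (0.0428).

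**Figure D1:**
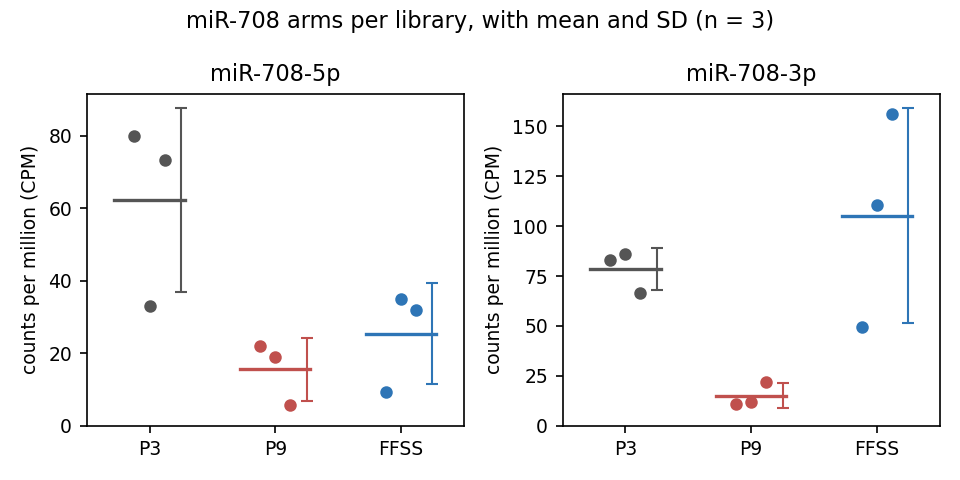
CPM of miR-708-5p and miR-708-3p in each library (points) of P3, P9 and FFSS, with the group mean (line) and SD (bar, n = 3). The P9 libraries lie at 5.63 to 22.1 CPM for miR-708-5p, below all P3 libraries, while FFSS replicate 2 at 34.9 CPM lies above P3 replicate 2 at 33.1 CPM.

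Passage 9 was compared with passage 3 to describe replicative senescence. Of the miR-34 family, transcribed under p53 and known to restrain the cell cycle, 4 of 6 measured members rose (camera adjusted p = 3.02e-08, and adjusted p = 0.0397 with an estimated correlation). All were arms of the miR-34b and miR-34c hairpins and so are not independent. miR-34c-5p went from 152 ± 2.71 to 989 ± 433 CPM (log2 fold change 2.72, SE 0.42, adjusted p = 0.00105) and miR-34b-3p from 19.8 ± 8.01 to 117 ± 25.6 CPM (2.63, SE 0.37, adjusted p = 6.52e-04). miR-143-3p, a miRNA of smooth muscle and fibroblasts and among the most abundant here, rose from 62078 ± 6073 to 154434 ± 22304 CPM (1.35, SE 0.24, adjusted p = 0.00348). miR-222-3p and miR-221-3p, which target the cell cycle inhibitor p27, rose by 1.07 and 0.93 on the log2 scale (adjusted p = 0.0134 and 0.0364). miR-195-5p, of the miR-15/16 family that represses cyclins, fell from 87.2 ± 33.7 to 14.1 ± 3.05 CPM (-2.58, SE 0.36, adjusted p = 6.52e-04).

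In all, 17 miRNAs were higher and 15 lower in P9 (16 and 15 by at least 2-fold) among 439 tested, and 76 had an unadjusted p under 0.05. The P9 and P3 libraries did not overlap for 25.3% of the miRNAs, where chance gives 10%. The naming rule also gave miR-598-3p (1.40, SE 0.34, adjusted p = 0.0218) and miR-146b-5p, a brake on NF-kB signalling (1.13, SE 0.31, adjusted p = 0.0419), among those that rose. Its paralog miR-146a-5p fell from 397 ± 4.51 to 26.3 ± 18.4 CPM (-3.82, SE 0.99, adjusted p = 0.0419), and the pair miR-378a-3p and miR-3557-5p, whose reads cannot be assigned to either, fell from 1741 ± 689 to 406 ± 83.5 CPM (-2.02, SE 0.37, adjusted p = 0.00395). Without P9 replicate 3, which stood apart from the other P9 libraries, the counts were 26 higher and 25 lower. They were 8 and 8 without P3 replicate 1, and without P3 replicate 3 they were 9 and 7. Leaving out P3 replicate 2 gave 11 higher, P9 replicate 1 gave 8 lower and P9 replicate 2 gave 9 lower.

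Of the 13 miRNAs that the rule named by fold change at passage 9, 7 kept their call in each of the 9 fits that left out 1 library: miR-34c-5p, miR-34b-3p, miR-143-3p, miR-195-5p, miR-708-3p and the pair miR-378a-3p and miR-3557-5p. miR-222-3p lost it without P3 replicate 1, 2 or 3 (adjusted p up to 0.0900, without P3 replicate 3). miR-598-3p lost it without any P3 library or P9 replicate 1 or 2 (up to 0.114, without P9 replicate 1). miR-146b-5p and miR-221-3p lost it without the same 5 libraries or FFSS replicate 3 (up to 0.224 without P3 replicate 1 for miR-146b-5p, and 0.153 without P9 replicate 1 for miR-221-3p). miR-146a-5p lost it without any P3 or P9 library (up to 0.249, without P9 replicate 1). The replicate block ended the calls on miR-146a-5p, miR-146b-5p and miR-221-3p, and log2(TPM + 1) those on miR-598-3p and miR-221-3p. Library size alone and log2(TPM + 10) also ended that on miR-221-3p, as did the required fold change. For miR-146a-5p upper-quartile factors, no filter, limma-voom, merged rows and both forms of thinning to the smallest total did so as well.

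Among the lists, 2 of 20 passed for passage 9. Of the 10 splits of these 6 libraries into 3 against 3, the real one included, 6 gave at least 2 lists. The number of lists past the test therefore does not set the real grouping apart. In the miR-34 family, 4 of 6 measured members rose, and 5 did when adjusted over the list alone (median log2 fold change 2.50; camera adjusted p = 3.02e-08, and adjusted p = 0.0397 with an estimated correlation). The 4 were miR-34c-5p, miR-34c-3p, miR-34b-3p and miR-34b-5p, the arms of the miR-34c and miR-34b hairpins, so they are not independent. miR-34a-5p did not pass, at 352 ± 65.3 CPM in P3 and 415 ± 215 CPM in P9 (0.26, adjusted p = 0.837). Its P9 libraries had 569, 506 and 169 CPM, and without P9 replicate 3, the lowest, the value was 0.62 (SE 0.35, adjusted p = 0.334). miR-34b-5p lost its call without P3 replicate 1 (adjusted p = 0.0979), P3 replicate 2 (0.0571), P3 replicate 3 (0.0673) or P9 replicate 2 (0.0543). In the miR-221 and miR-222 list, 2 of 4 members rose, and 3 when adjusted over the list alone (median 0.94; camera adjusted p = 0.0280, and adjusted p = 0.322 with an estimated correlation). Its call was lost without P9 replicate 3 (adjusted p = 0.127), which left 1 list past the test, and without P3 replicate 2 the number was 4.

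The other lists did not pass. Of 12 measured miRNAs reported up in senescence, 3 rose, miR-34c-5p, miR-34b-5p and miR-146b-5p, and miR-146a-5p fell, the same count adjusted over the list alone (camera adjusted p = 0.340). In the chondrocyte and cartilage list 0 of 10 members passed, though 2 were lower adjusted over the list alone (camera adjusted p = 0.0823, 8 members negative). These were miR-140-5p and miR-140-3p, made from a cartilage gene, with values of -1.12 (SE 0.34, adjusted p = 0.0679) and -0.86 (SE 0.27, adjusted p = 0.0763). At an unadjusted p under 0.05 there were 3 members, and DESeq2 called 1 and limma-voom 0. Of 14 NF-kB and inflammation miRNAs, miR-146b-5p rose and miR-146a-5p fell, against 3 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.0823). Among 6 members of the miR-15/16 family, miR-195-5p and miR-497-5p fell, 2 also adjusted over the list alone (camera adjusted p = 0.129). Of 10 fibroblast and smooth muscle miRNAs, miR-143-3p rose, and 3 were higher adjusted over the list alone (camera adjusted p = 0.156). Among 16 shear or stretch responsive miRNAs, miR-143-3p, miR-222-3p and miR-221-3p rose and miR-146a-5p fell, against 4 higher and 2 lower adjusted over the list alone (camera adjusted p = 0.734). The mean of this list was -0.015, its median 0.064 with the scaling used and -0.003 at the lowest of the other scalings.

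No member passed in the remaining lists for passage 9 with edgeR, neither over all miRNAs nor adjusted over the list alone. These were the Dlk1-Dio3 locus (0 of 65, median 0.35, camera adjusted p = 0.0823), the let-7 and miR-98 family (0 of 9, median -0.27, 0.127), the miR-23/27/24 clusters (0 of 11, median -0.17, 0.216), the miR-322 and miR-503 cluster (0 of 12, median 0.29, 0.340) and the miR-17-92 clusters (0 of 14, median 0.055 with camera pointing down, 0.952). The miR-29 (0 of 6), miR-30 (0 of 5) and miR-181 (0 of 4) families had camera adjusted p of 0.989, 0.965 and 0.695, with a median of -0.13 and a mean of 0.098 for miR-30. The markers of other cell types gave 0 of 5 for blood (camera adjusted p = 0.805), 0 of 7 for epithelium (0.438), 0 of 5 for muscle (0.685) and 0 of 7 for the nervous system (0.924), where median and mean had opposite signs and the median turned negative under another scaling. miR-210-3p of the hypoxia list (paired with miR-3574), miR-126a-3p of endothelium and miR-122-5p of liver had values of 0.41, -0.08 and 0.04 and did not pass. At an unadjusted p under 0.05 stood 2 Dlk1-Dio3, 2 let-7, 2 miR-23/27/24, 2 miR-181, 1 miR-30 and 1 miR-322 and miR-503 cluster member, and 0 of the miR-17-92, miR-29 and other cell type lists. DESeq2 called 1 let-7 member and 0 in the rest, and limma-voom 0 in all of these lists. In P9 replicate 3, however, 7 of 10 markers of blood, liver and muscle lay above each P3 library and 3 below. miR-1b stood there at 462 CPM (112 to 126 CPM in the P3 libraries and the other P9 libraries), miR-133a-3p, whose reads cannot be told from those of miR-133c, at 40.4 CPM (8.24 to 10.9) and miR-122-5p at 22.9 CPM (3.43 to 11.7). P9 replicates 2 and 3 had 122.8 and 117.4 CPM of miR-451-5p (24.5 to 85.2 CPM in P3) and 170.7 and 181.5 CPM of miR-486 (44.9 to 67.4 CPM in P3).

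**Figure D2:**
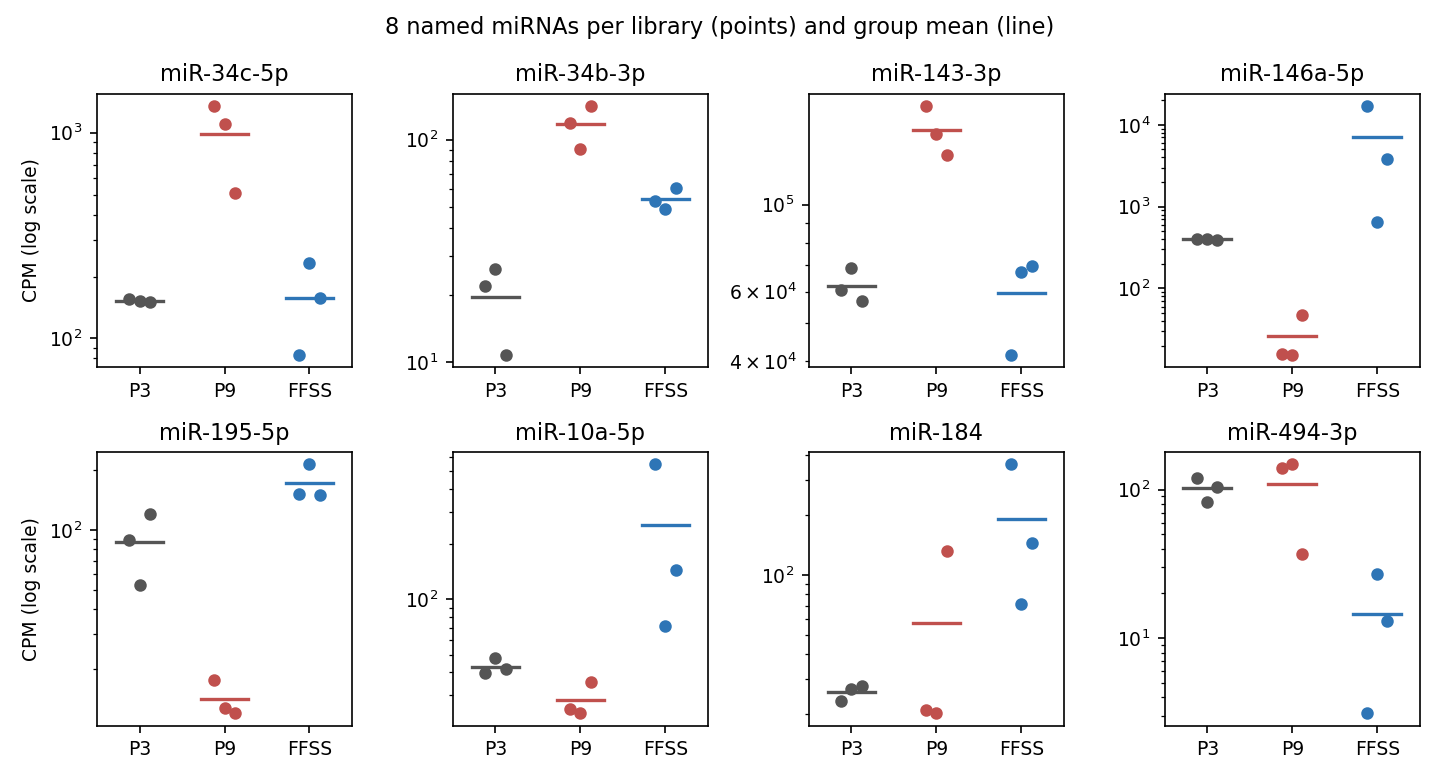
CPM on a log scale of 8 named miRNAs in each library (points) of P3, P9 and FFSS, with the group mean (line). miR-34c-5p lies at 508 to 1350 CPM in P9 and at 83.4 to 234 CPM in the other libraries, and miR-146a-5p at 15.5 to 47.6 CPM in P9, 392 to 401 CPM in P3 and 650.2 to 17002 CPM in FFSS.

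Shear-stressed passage 3 cells were compared with the P3 control to describe degeneration under mechanical load. Of 65 measured miRNAs of the imprinted Dlk1-Dio3 locus, expressed from the maternal chromosome as long shared transcripts, 37 fell (camera adjusted p = 7.32e-27, and adjusted p = 0.143 with an estimated correlation). Among them, miR-494-3p went from 102 ± 18.5 to 14.4 ± 12.05 CPM (log2 fold change -2.81, SE 0.63, adjusted p = 0.00985), and miR-493-5p from 95.5 ± 30.8 to 22.7 ± 6.15 CPM (-2.12, SE 0.33, adjusted p = 0.00636). miR-221-5p fell from 423 ± 37.9 to 107 ± 18.9 CPM (-2.01, SE 0.34, adjusted p = 0.00636). miR-146a-5p, induced by NF-kB, rose from 397 ± 4.51 to 7168 ± 8665 CPM (4.20, SE 0.999, adjusted p = 0.0198), with 17002, 650.2 and 3853 CPM in the FFSS libraries. miR-10a-5p, from a HoxB cluster, rose from 42.9 ± 4.15 to 254 ± 255 CPM (2.57, SE 0.63, adjusted p = 0.0167).

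In all, 30 miRNAs were higher and 60 lower in FFSS (27 and 55 by at least 2-fold), and 159 had an unadjusted p under 0.05. The libraries did not overlap for 41.5% of the miRNAs, where chance gives 10%. By the naming rule miR-184, miR-224-5p, miR-30a-3p, miR-34b-3p, miR-30c-2-3p and miR-132-3p also rose, by 2.87 to 1.08 on the log2 scale, as did the pair miR-9a-5p and miR-9b-3p (1.21 and 1.22). The rule further gave miR-541-5p (-2.22), miR-543-3p (-2.18) and miR-370-3p (-1.81), and the pairs miR-382-3p and miR-3592 (-1.97 and -1.96) and miR-409a-3p and miR-409b (-1.93 and -1.92), which fell. miR-154-3p had 0 reads in FFSS against 3.05 CPM in P3 and was at least 14.1-fold lower.

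Without FFSS replicate 1, the shallowest library, 18 miRNAs were higher and 59 lower, and without FFSS replicate 3 the counts were 8 and 32. The counts were 3 and 33 without P3 replicate 1, 7 and 38 without P3 replicate 2, and 53 and 94 without P9 replicate 3. The number higher was 6 without P3 replicate 3, 18 without P9 replicate 1 and 12 without P9 replicate 2. It was also 15 with no filter, 16 with libraries thinned to the smallest total, 9 with the replicate block and 51 in a fit of only P3 and FFSS, while the number lower was 39 with a mean of at least 50 counts.

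Of the 20 miRNAs named by fold change under shear stress, 8 kept their call in each of the 9 fits that left out 1 library: miR-541-5p, miR-493-5p, miR-221-5p, miR-370-3p, and the pairs of miR-382-3p and miR-409a-3p. miR-494-3p lost it without FFSS replicate 3 (adjusted p = 0.0514), miR-30a-3p without P3 replicate 1 (0.0630) and miR-543-3p without P3 replicate 2 or FFSS replicate 1 or 3 (up to 0.0889). The call on miR-146a-5p was lost without any P3 library or P9 replicate 3 (up to 0.0900), with no filter, limma-voom, a fit of only P3 and FFSS, the replicate block, and thinning with the miRNAs of the full counts kept. miR-184 lost it without any P3 library or FFSS replicate 1 (up to 0.110) and with no filter, miR-10a-5p without P3 replicate 1 or 3 or FFSS replicate 1 (up to 0.0820) and with the block. miR-224-5p lost it without any P3 library or FFSS replicate 1 or 3 (up to 0.110), and miR-34b-3p without P3 replicate 1 or 3 or FFSS replicate 3 (up to 0.102). miR-132-3p and the miR-9a-5p pair lost it without any P3 library, P9 replicate 1 or 2, or FFSS replicate 1 or 3 (up to 0.184 and 0.214), and miR-30c-2-3p without any P3 library, P9 replicate 1 or 2, or FFSS replicate 2 or 3 (up to 0.128). These last also lost it with the replicate block and with no filter. miR-30c-2-3p further lost it on log2(TPM + 1) and log2(TPM + 10), and miR-132-3p thinned to the smallest total with the filter applied again. The miR-9a-5p pair lost it without the 10 most abundant miRNAs and in limma-voom, and miR-9b-3p in both forms of thinning too.

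Of 20 lists, 1 passed under shear stress. Of the 10 splits of these 6 libraries into 3 against 3, the real one included, 9 gave at least 1 list, so this number does not set the real grouping apart. Of 65 measured Dlk1-Dio3 miRNAs (90 in the table), 37 fell and 51 did when adjusted over the list alone (median log2 fold change -1.51, also with miR-154-3p at its bound; camera adjusted p = 7.32e-27, and adjusted p = 0.143 with an estimated correlation). With the pair miR-409a-3p and miR-409b counted once, 36 of 64 fell, and 50 adjusted over the list alone. In all, 64 of the 65 had a negative value. The median difference from the P3 mean was -2.27 in FFSS replicate 1, -1.05 in FFSS replicate 2 and -1.06 in FFSS replicate 3, against 0.19 to 0.34 in the P9 libraries. The number that fell was 23 without P3 replicate 1, P3 replicate 2 or FFSS replicate 3, 30 without FFSS replicate 1 and 51 without P9 replicate 3. Beside this, FFSS replicates 1 and 3 carried more of the blood miRNA miR-451-5p, at 276 and 180.2 CPM against 24.5 to 85.2 CPM in P3, and of the liver miRNA miR-122-5p, at 51.4 and 30.5 CPM against 9.87 to 11.7 CPM. The number of lists past the test was 3 without P3 replicate 2 or FFSS replicate 2, and 2 without P9 replicate 1.

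**Figure D3:**
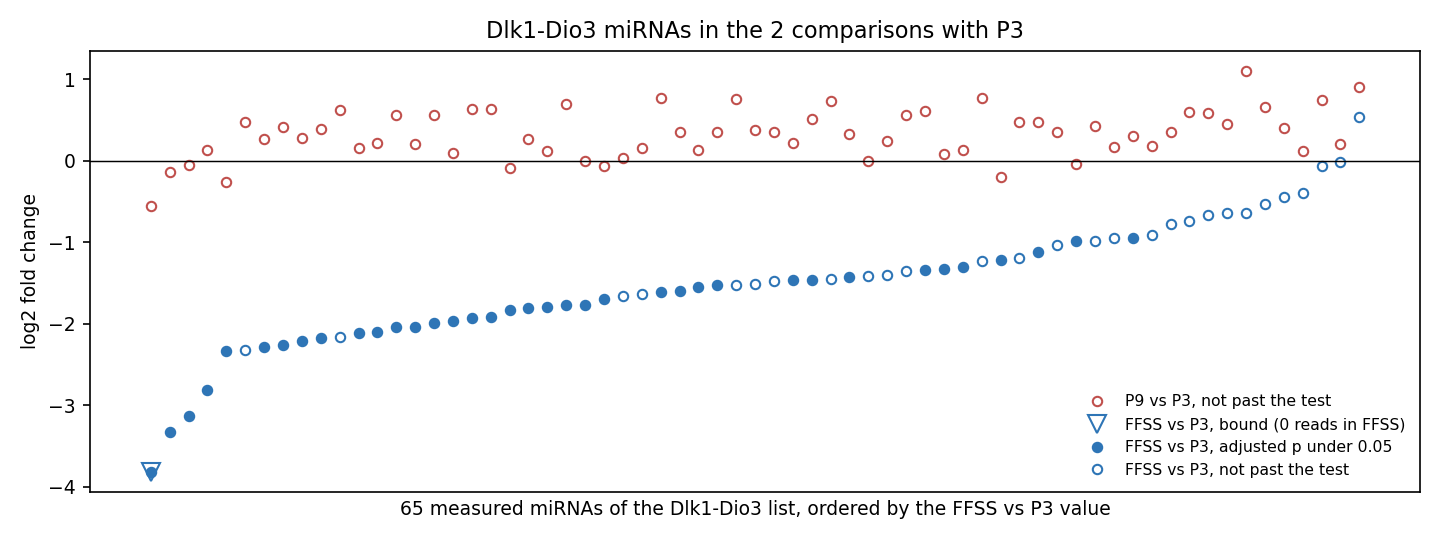
Log2 fold changes against P3 of the 65 measured Dlk1-Dio3 miRNAs, ordered by the value under shear stress (blue, FFSS against P3; red, P9 against P3); filled points passed the test and the triangle marks a bound for miR-154-3p. Under shear stress 37 passed, all lower, with a median of -1.51, and at passage 9 0 passed, with a median of 0.35.

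Other lists did not pass for shear stress. Of 14 NF-kB and inflammation miRNAs 5 rose, against 5 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.0939). They were miR-146a-5p, miR-132-3p, miR-9a-5p (paired with miR-9b-3p), miR-9a-3p and miR-147, the last at 1.24 ± 0.68 CPM in P3 and 3.36 ± 1.41 CPM in FFSS. In the miR-34 family 2 of 6 rose, also 2 adjusted over the list alone: miR-34c-3p (1.65) and miR-34b-3p (1.40), while miR-34c-5p was at 158 ± 75.1 CPM (0.00, adjusted p = 0.993; camera adjusted p = 0.0997). In the miR-23/27/24 clusters 3 of 11 rose, miR-23a-3p (0.79), miR-24-3p (0.84) and miR-23a-5p (1.65), and 4 adjusted over the list alone (camera adjusted p = 0.103). In the miR-221 and miR-222 list 2 of 4 fell, miR-221-5p and miR-222-3p (-0.92), and 3 adjusted over the list alone (camera adjusted p = 0.103). Of 14 members of the miR-17-92 clusters, which drive proliferation, miR-20a-5p (-1.72), miR-17-5p (-1.18) and miR-19a-3p (-3.39) fell, against 1 higher and 5 lower adjusted over the list alone (camera adjusted p = 0.544). miR-19a-3p had 2.26 to 4.28 CPM in P3 and 0 to 0.513 CPM in FFSS. That is under 3 counts in each FFSS library, so the size of its fold is uncertain. Of 10 fibroblast and smooth muscle miRNAs, miR-10a-5p rose while miR-145-5p (-1.57), miR-10b-5p (-1.57) and miR-10b-3p (-1.48) fell, the same number adjusted over the list alone (camera adjusted p = 0.486). The list of 16 shear or stretch responsive miRNAs had 2 higher, miR-10a-5p and miR-146a-5p, and 3 lower, miR-145-5p, miR-19a-3p and miR-222-3p, against 3 and 6 adjusted over the list alone (camera adjusted p = 0.486).

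Of 12 senescence miRNAs, miR-146a-5p rose and miR-494-3p fell, 1 each also adjusted over the list alone (camera adjusted p = 0.669). In the miR-322 and miR-503 cluster miR-450a-5p (-1.13) and miR-450b-5p (-0.99) fell of 12, 2 also adjusted over the list alone (camera adjusted p = 0.497). In the chondrocyte list miR-337-5p (-1.30) fell of 10 and in the let-7 and miR-98 family miR-98-5p (-0.85) fell of 9, both 0 adjusted over the list alone (camera adjusted p = 0.669 and 0.856). No member of the miR-29 (0 of 6), miR-15/16 (0 of 6), miR-30 (0 of 5) or miR-181 (0 of 4) families passed with edgeR, and 0 did adjusted over the list alone (camera adjusted p = 0.460, 0.669, 0.486 and 0.754), and the miR-181 median of 0.006 changed sign with the scaling. At an unadjusted p under 0.05 there were 1, 1, 2 and 0 members in this order, and DESeq2 called 1, 1, 2 and 0 and limma-voom 0 in each. Of the blood markers miR-142-5p rose (1.53), 1 of 5 against 4 adjusted over the list alone, with a median of 1.53 (camera adjusted p = 0.0694). Of the epithelial markers miR-200b-3p rose (1.53), 1 of 7 and 1 adjusted over the list alone (camera adjusted p = 0.152), and in the nervous system list miR-9a-3p and the pair miR-9a-5p and miR-9b-3p rose, 3 of 7 and 3 adjusted over the list alone, or 2 of 6 and 2 with the pair counted once (camera adjusted p = 0.393). Muscle markers gave 0 of 5, 0 also adjusted over the list alone (median 0.77, camera adjusted p = 0.393), with 1 at an unadjusted p under 0.05 and 0 in DESeq2 and limma-voom. miR-122-5p of liver, miR-210-3p of hypoxia (paired with miR-3574) and miR-126a-3p of endothelium had values of 1.57, 1.14 and 0.61 and did not pass (adjusted p = 0.121, 0.197 and 0.192), though miR-122-5p did adjusted over the list alone, 1 of 1.

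The direct contrast of P9 with FFSS tests whether both changes from P3 differ. miR-34c-5p was higher in P9 (log2 fold change 2.72, SE 0.42, adjusted p = 6.87e-04), as were miR-494-3p (2.94), miR-10b-5p (2.71), miR-221-5p (2.68) and miR-145-5p (2.61), the last at 11896 ± 5132 CPM against 2047 ± 705 CPM. miR-146a-5p was lower in P9 (-8.02, SE 1.19, adjusted p = 7.24e-04), and so were miR-195-5p (-3.53), miR-10a-5p (-3.11), miR-224-5p (-3.07) and miR-149-5p (-2.99). These 10 kept their call in each fit that left out 1 library and under each other setting. In all 99 miRNAs were higher and 52 lower in P9, so 65.6% of the calls were higher, 55% with upper-quartile factors (94 higher, 77 lower), which moved the median of all miRNAs by -0.111. Of the miRNAs, 42.8% did not overlap, where chance gives 10%.

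In this contrast 55 of 65 Dlk1-Dio3 miRNAs were higher in P9, and 57 adjusted over the list alone (median 1.83, camera adjusted p = 1.96e-22, and adjusted p = 0.158 with an estimated correlation). The numbers were 54 of 64 and 56 with the pair miR-409a-3p and miR-409b counted once. Of the miR-221 and miR-222 list, 3 of 4 were higher, and 4 adjusted over the list alone (median 1.79, camera adjusted p = 0.00367, and adjusted p = 0.197 with an estimated correlation). Of the miR-23/27/24 clusters, 4 of 11 were lower, miR-23b-3p, miR-23a-3p, miR-23a-5p and miR-24-3p, and 5 adjusted over the list alone (median -0.60, camera adjusted p = 0.0308, and adjusted p = 0.361 with an estimated correlation). The other 17 tested lists did not pass. At least 3 lists passed in 6 of the 10 splits of these 6 libraries into 3 against 3, the real one included. Of the blood markers miR-142-5p was lower in P9, 1 of 5 against 0 adjusted over the list alone (all 5 negative, median -1.08, camera adjusted p = 0.192). Of the epithelial markers miR-203a-3p and miR-203b-5p were lower, 2 of 7 and 2 adjusted over the list alone (all 7 negative, median -0.83, camera adjusted p = 0.123). In the nervous system list miR-9a-3p was lower, 1 of 7 against 3 adjusted over the list alone, or 1 of 6 and 1 with the pair miR-9a-5p and miR-9b-3p counted once (median -0.54, camera adjusted p = 0.381). Muscle markers gave 0 of 5, 0 also adjusted over the list alone, at an unadjusted p under 0.05, in DESeq2 and in limma-voom (median -0.11, camera adjusted p = 0.658). miR-122-5p of liver and miR-126a-3p of endothelium had values of -1.53 and -0.69 and did not pass (adjusted p = 0.101 and 0.110), though miR-122-5p did adjusted over the list alone, 1 of 1, and in DESeq2 and limma-voom. The call on the miR-23/27/24 clusters was lost without P3 replicate 3 (0.0518), P9 replicate 2 (0.0636), FFSS replicate 2 (0.0627) or FFSS replicate 3 (0.0612), and thinned to the smallest total with the filter applied again (0.0516). Without P9 replicate 3 the counts of miRNAs were 123 higher and 80 lower, and without FFSS replicate 1 they were 102 and 48. The number lower was 33 without P3 replicate 1, 30 without P9 replicate 1, 28 without P9 replicate 2 and 31 without FFSS replicate 3. It was 81 on log2(TPM + 10), 28 in a fit of only P9 and FFSS and 33 thinned in the same way.

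The study asked what replicative senescence and shear stress have in common. In both comparisons with P3, miR-34c-3p, miR-34b-3p and miR-92b-3p rose. The more abundant arm miR-34c-5p passed at passage 9 but not under shear stress. There it was at 158 ± 75.1 CPM, against 152 ± 2.71 CPM in P3 (log2 fold change 0.00, adjusted p = 0.993). miR-34c-3p went from 6.68 ± 0.91 CPM in P3 to 33.5 ± 6.24 in P9 and 21.7 ± 4.74 in FFSS, and miR-92b-3p from 3.02 ± 0.90 to 7.09 ± 1.32 and 11.9 ± 2.39 CPM. miR-1247-3p fell in both, from 9.70 ± 1.99 to 0.59 ± 0.24 and 2.47 ± 1.90 CPM, while miR-146a-5p and miR-222-3p moved in opposite directions. These 3 higher, 1 lower and 2 opposite compare with 1.16, 2.05 and 3.35 for independent lists of these sizes, so only the number higher lay above. That number includes miR-34c-3p and miR-34b-3p, which are not independent. Simulations of unchanged groups against the same controls gave 0.01, 0 and 0. With no miRNA changed few calls can arise, so these simulations are no reference for an overlap among real calls. The 3 control libraries cannot be split into parts of at least 2 libraries each, so part of any excess may come from the shared controls.

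Across all 439 miRNAs, which are not independent replicates, the fold changes of both comparisons had a Pearson correlation of 0.011 and a Spearman correlation of -0.012, against 0.488 ± 0.048 and 0.465 ± 0.039 in the simulations. The covariance was 0.0116 against a simulated 0.107 ± 0.0158, a difference of -0.0954, and 47.8% of the miRNAs had the same sign against 66.5%. In the simulations all fold changes are noise, so their correlations and share of the same sign are no expectation for groups with real changes. The number higher in both was 1 without P3 replicate 1, P3 replicate 3 or FFSS replicate 3, 5 without FFSS replicate 1 and in DESeq2, and 4 without P9 replicate 3. The number lower in both was 0 without any 1 of the P3 libraries or FFSS replicate 3, 4 without P9 replicate 3 and 2 without FFSS replicate 1. It was 3 with no filter and in fits of only the 2 groups compared, 0 with a mean of at least 50 counts, 4 in DESeq2 and 2 on log2(TPM + 10). miR-92b-3p had an adjusted p of 0.0490 at passage 9 and lost this call without any 1 of the P3 or P9 libraries, FFSS replicate 2 or FFSS replicate 3 (up to 0.179). It also lost it with upper-quartile factors, library size alone, no filter, limma-voom, both TPM scales, fits of only the 2 groups compared, the replicate block and both forms of thinning. In the test of miR-1247-3p FFSS vs P3 the call was lost without P3 replicate 1 (adjusted p = 0.0744), P3 replicate 2 (0.0592), P3 replicate 3 (0.0769) or FFSS replicate 3 (0.0862), and in that of miR-222-3p FFSS vs P3 without P3 replicate 1 (0.0505) or FFSS replicate 3 (0.0622).

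**Figure D4:**
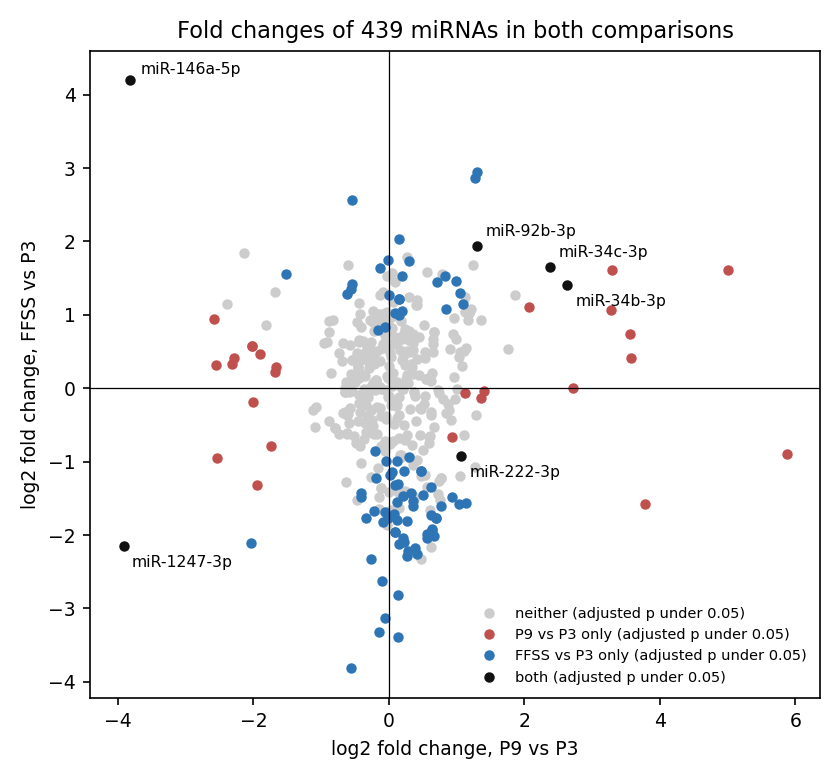
Log2 fold change under shear stress (FFSS against P3) plotted against that at passage 9 (P9 against P3) for 439 miRNAs, coloured by the comparison in which each passed an adjusted p of 0.05. The 6 black points passed in both: miR-34c-3p, miR-34b-3p and miR-92b-3p higher in both, miR-1247-3p lower in both, and miR-146a-5p and miR-222-3p opposite.

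The balance between the arms of a hairpin was compared as the log2 ratio of 5p to 3p counts. Under shear stress the balance of miR-376b shifted toward 5p, from -0.64 ± 0.45 to 1.67 ± 0.23 (change 2.31, SE 0.37, limma adjusted p = 0.00384). It shifted toward 3p for miR-152 (-1.93, adjusted p = 0.0144), miR-362 (-1.93, adjusted p = 0.0195) and miR-34c (-1.75, adjusted p = 0.0357), the last from 4.51 ± 0.16 to 2.76 ± 0.67. Of 89 hairpins, 1 moved toward 5p and 3 toward 3p, and 28 had an unadjusted p under 0.05. At passage 9 limma called 0 hairpins in either direction, with 2 at an unadjusted p under 0.05. With an offset of 5 in place of 0.5, the counts under shear stress were 2 and 7. They were 10 and 22 without P9 replicate 3, and the number toward 3p was 0 without P3 replicate 2, 5 without FFSS replicate 1 or FFSS replicate 2, and 1 without FFSS replicate 3.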

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

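Of the tests of explanations here, the depth and scaling tests of the Dlk1-Dio3 locus, the tests of a common source of blood, liver and muscle miRNAs and the tests of P9 replicate 3 were chosen after the results were seen. Of 31 named miRNAs, 24 differed directly between P9 and FFSS, with both rows of a near-identical pair counted, against 151 of all 439 miRNAs. The 31 were picked for large changes from P3 in these libraries, so a larger share was built in. In that contrast 3 lists passed with the preset correlation. None of the 3 lists passed with an estimated correlation (adjusted p = 0.158 for the Dlk1-Dio3 locus, 0.197 for the miR-221 and miR-222 list and 0.361 for the miR-23/27/24 clusters). Groups of 3 libraries are too small for a test of outliers. On the log2 scale, P9 was above FFSS by 2.72 for miR-34c-5p, 1.23 for miR-34b-3p, 1.44 for miR-598-3p, 1.48 for miR-143-3p, 1.19 for miR-146b-5p, 1.99 for miR-222-3p and 1.59 for miR-221-3p. It was also above by 2.94 for miR-494-3p, 2.50 for miR-541-5p, 2.57 for miR-543-3p, 2.27 for miR-493-5p, 2.68 for miR-221-5p, 2.06 and 2.05 for the pair miR-382-3p and miR-3592, 2.56 and 2.55 for the pair miR-409a-3p and miR-409b, and 2.08 for miR-370-3p. The difference was -2.64 for miR-708-3p, -8.02 for miR-146a-5p, -3.53 for miR-195-5p, -2.60 for both miR-3557-5p and miR-378a-3p, -3.11 for miR-10a-5p and -3.07 for miR-224-5p. The median difference was 1.83 for the Dlk1-Dio3 locus, -0.60 for the miR-23/27/24 clusters and 1.79 for the miR-221 and miR-222 list.

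The Dlk1-Dio3 miRNAs had a median of -1.51 under shear stress. Lower depth, other scalings and a loss of rare miRNAs were argued against as the whole cause: the median over all 65 members was -1.482 with every library thinned to the smallest total (-1.772 for the 9 that the filter would drop there), at most -1.453 under 4 other scalings, and 10000 lists outside the locus matched on the P3 mean had a middle of 0.274, with 0 as low as the locus and a lowest of -0.364. Members of the matched lists were drawn 1 by 1, so these lists lack the correlation among members of the locus, estimated at 0.23. Their spread is therefore too narrow a reference, and only their middle bears on a loss of rare miRNAs. The locus was lowest in FFSS replicate 1, at -2.27, and its camera call was lost with an estimated correlation (adjusted p = 0.143). A different mix of cells in the FFSS cultures, a technical difference between the FFSS and P3 libraries and an effect of shear stress itself stay open. No test here separates them. The locus may respond to shear stress, a hypothesis found and tested on the same libraries.

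Of 10 markers of blood, liver and muscle, all 10 lay above each P3 library in FFSS replicates 1 and 3, 7 in FFSS replicate 2 and 7 in P9 replicate 3, the last with miR-1b at 462 CPM and 3 markers below each P3 library, against 3 and 2 above in P9 replicates 1 and 2. The libraries with more miR-451-5p than each P3 library were P9 replicates 2 and 3 and FFSS replicates 1 and 3, and over these 4 the ratio of miR-122-5p to miR-451-5p varied by 6.969-fold, but by 1.149-fold without P9 replicate 2, against 3.02-fold among the P3 libraries. The ratios of miR-1b and miR-133a-3p (paired with miR-133c) to miR-451-5p varied by 3.906-fold and 5.03-fold, against 3.115-fold and 4.57-fold among the P3 libraries, but by 1.643-fold and 1.605-fold without P9 replicate 3, so in both tests the spread rests on 1 library, and 1 common source of the blood and liver miRNAs, or of the muscle and blood miRNAs, stays open. A lower yield of the cells' own miRNAs in the shallow libraries is a candidate explanation, since the median Spearman correlation of these 10 markers with the library total over 9 libraries was -0.625. However, 2 of the 3 FFSS libraries are the shallow ones and P9 replicate 3 is not shallow, and no biological explanation was tested.

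P9 replicate 3 stood apart from P9 replicates 1 and 2, with miR-99a-5p at 118982 CPM against 23009 and 27543 CPM. Its log CPM correlated at 0.969 with P3 replicate 2, above the 0.956 and 0.963 with P9 replicates 1 and 2. With P3 replicates 1 and 3 the correlation was 0.956 and 0.946. Lower depth was argued against, as its total was 8.177 M reads, above both other P9 libraries. An exchanged label with a P3 library was argued against by its median position of 0.516 between P3 (0) and P9 replicates 1 and 2 (1) over 51 miRNAs (quartiles 0.063 and 0.858), where each P3 library, left out in turn, had a median of -0.043 to 0.071. A mixture with passage 3 cells was argued against as the whole cause, since 5 of 169 miRNAs, miR-1b and miR-129-5p above and miR-340-5p, miR-374-5p and miR-494-3p below, lay more than 2-fold outside the range of the other P3 and P9 libraries, and 0 did so in each of those. Each of those other libraries had a close replicate within the range, so their 0 is a weak reference. The median position of 0.516 is one that a mixture could also give, so a mixture as part of the cause stays open. A difference between cultures stays open as well and was not tested.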

How the results depend on the processing

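Merged near-identical rows and both forms of thinning to the smallest total were chosen after the data were seen. No call took the opposite direction under any setting tried, and the cause of the following differences was not tested unless a setting has fewer miRNAs or libraries by construction. The values of single miRNAs and hairpins were counted together with the Pearson correlation of both sets of fold changes across miRNAs. Outside the fits that left out 1 library, 900 stayed the same, 49 dropped below the threshold and 2 rose past it. The correlation moved by at least its simulated SD of 0.048 in 5 of these settings. In the fits that left out 1 library, 493 stayed the same, 95 dropped below the threshold and 3 rose past it. The correlation moved as much in 3 of these fits. DESeq2 gave no adjusted p for 9 miRNAs in FFSS against P3. Depth limits the rarest miRNAs: 3 counts correspond to 0.339 CPM in the deepest and 1.04 CPM in the shallowest library.

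With no filter, 15 miRNAs were higher in FFSS than P3, 3 were lower in both comparisons, and miR-708-5p reached -1.43 in FFSS. With a mean of at least 50 counts, 39 were lower in FFSS, 0 lower in both, and miR-708-5p was -1.83 in P9 (fewer miRNAs tested). DESeq2 gave 5 higher and 4 lower in both and -1.29 for miR-708-5p in FFSS. On log2(TPM + 1) miR-708-5p was -2.025 in P9, and on log2(TPM + 10) 81 miRNAs were lower in P9 than FFSS and 2 lower in both. Fits of only the 2 groups compared gave 51 higher in FFSS than P3, 28 lower in P9 than FFSS, 3 lower in both, and -1.31 for miR-708-5p in FFSS. Thinned to the smallest total, 16 were higher in FFSS, 33 lower in P9 than FFSS, and the miR-23/27/24 clusters had an adjusted p of 0.0516. Camera with an estimated correlation left 1, 0 and 0 lists for P9 against P3, FFSS against P3 and P9 against FFSS. Its adjusted p was 0.322 for miR-221 and miR-222 in P9 against P3, 0.143 for Dlk1-Dio3 in FFSS against P3, and in P9 against FFSS 0.158 for Dlk1-Dio3, 0.361 for the miR-23/27/24 clusters and 0.197 for miR-221 and miR-222. Fry, which does not compare a list with other miRNAs, gave 4 lists for FFSS against P3 and 6 for P9 against FFSS. In P9 against P3 its adjusted p was 0.00356 for the miR-34 family, 0.00378 for miR-221 and miR-222 and 0.00391 for NF-kB and inflammation. This last list, which camera did not call, pointed up by fry in FFSS against P3 too (adjusted p = 0.00446). Its member miR-146a-5p moved in opposite directions in these comparisons. An offset of 5 gave 2 hairpins toward 5p and 7 toward 3p.

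The replicate block gave 9 higher in FFSS than P3 and -2.01 for miR-708-5p in P9 (adjusted p = 0.0722). Same-numbered libraries showed no common shift: their deviations from their group means correlated at 0.09, -0.29 and -0.47 for P3 and P9, -0.09, 0.12 and -0.13 for P3 and FFSS, and -0.10, 0.06 and 0.04 for P9 and FFSS. Deviations from means of 3 libraries cannot tell whether same-numbered libraries share a source.

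Leaving out 1 library gave 8 (P3 replicate 1) to 26 (P9 replicate 3) higher and 7 (P3 replicate 3) to 25 (P9 replicate 3) lower in P9 than P3. It gave 3 (P3 replicate 1) to 53 (P9 replicate 3) higher and 32 (FFSS replicate 3) to 94 (P9 replicate 3) lower in FFSS than P3. In P9 against FFSS, 28 (P9 replicate 2) to 80 (P9 replicate 3) were lower. The number higher in both ran from 1 to 5 and lower in both from 0 to 4. miR-708-5p ran from -2.20 to -1.56 in P9 and from -1.78 to -1.07 in FFSS. Lists past the test ran from 1 to 4 for P9 against P3, 1 to 3 for FFSS against P3 and 2 to 4 for P9 against FFSS. The adjusted p ran from 0.0187 to 0.127 for miR-221 and miR-222 in P9 against P3 and from 0.0124 to 0.0636 for the miR-23/27/24 clusters in P9 against FFSS. Hairpins under shear stress ran from 1 to 10 toward 5p and 0 to 22 toward 3p.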

Other observations

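The miRNAs in this paragraph were chosen after their values were seen; the tests of neighbouring genes and of other splits were planned. miR-592 rose from 0.518 to 31.9 ± 22.8 CPM (log2 fold change 5.87, SE 0.83, adjusted p = 6.52e-04), with 50.7, 38.5 and 6.48 CPM in the P9 libraries and 0.265 CPM in FFSS. From P3 to P9, miR-130b-5p rose from 0.248 ± 0.141 to 7.92 ± 3.61 CPM (adjusted p = 5.02e-04), miR-325-5p from 0.926 ± 0.0917 to 8.88 ± 2.30 CPM (adjusted p = 5.02e-04) and miR-384-3p from 0.254 ± 0.240 to 3.43 ± 1.36 CPM (adjusted p = 0.00454). Also at passage 9, both arms of miR-195, at 36.9 and 6.91 CPM in P3 and P9 for miR-195-3p (-2.28), fell with their genomic neighbour miR-497-5p (-2.56), and both arms of miR-298 fell too (-2.54 and -1.75). Under shear stress, the paralogs miR-10a-5p and miR-10b-5p went opposite ways (2.57 and -1.57), and miR-7a-5p fell from 6035 to 1878 CPM (-1.72).

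Neighbouring miRNA genes may change together because they are transcribed as 1 unit. Outside the Dlk1-Dio3 locus, 69 pairs of hairpins within 10 kb of each other had fold changes that correlated at 0.855 in P9 against P3 (Spearman 0.747) and 0.672 in FFSS against P3 (Spearman 0.673). The permutation p was 1e-05 in both, the smallest that 100000 permutations can give, across genes that are not independent replicates. Positions were those of a later genome build, in which 271 of 312 hairpins were matched by name. A hairpin that shares reads with its neighbour would raise the correlation too, and this was not tested.

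For the other splits of the libraries, 3 against 3 gives 10 splits, too few for a share under 0.05. A count of miRNAs as large was found in 1 split for each comparison, the real one, with 32 calls for P9 against P3, 90 for FFSS against P3 and 151 for P9 against FFSS, and 0 as the highest other in each. For lists, 6, 9 and 6 splits gave as many as the real 2, 1 and 3, with 4 as the highest other in each comparison. For arm balance, 10 splits reached the real 0 in P9 against P3 (highest other 0) and 1 split the real 4 in FFSS against P3 (highest other 0). For miRNAs changed in both comparisons, 4 of 100 splits of the 9 libraries, the real one included, gave at least the real 4. The highest other was 72, and each of the others kept a real group whole as the control, which points to the structure of the samples. The share is under 0.05, but the splits of 6 libraries that mixed the groups gave 0 calls. A low share was therefore likely whatever the real overlap and does not speak for a shared response.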
